A study of Mus musculus with 4 samples.

How the data were processed

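The data were 4 RNA-seq libraries of mouse T cells, 2 grown under Th9 conditions and 2 under Th9 conditions with TL1A; the sample labels write TLA1 and the series title TL1A, read here as the same cytokine. Per the labels' protocols, total RNA was turned into cDNA with a SMARTer Ultra Low Input kit, fragmented, and sequenced on an Ion Torrent instrument; that kit does not mark strand. The submitters' processing notes name HTSeq 0.5.4, edgeR and the mouse build mm10. The aligner and the gene annotation are not given in the sources used here. The values the authors deposited are CPM, reads scaled to the same total over genes in every library, with 1 file per library and 23480 gene identifiers in each. Each library's values were whole multiples of what 1 read is worth, so 100% of non-zero values gave whole reads within a tolerance of 0.01 of a read. These recovered reads came to 4041633 and 3167270 for Th9 and 2979482 and 3081187 for Th9 with TL1A, and the 100 most abundant genes took 15.8% to 20.1% of them. Reads from amplified low-input cDNA are not independent molecules, so floors and counts cover counting error only.

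Gene symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly of mm10, which matched 23383 of the 23480 identifiers. Counts had been assumed when the tests were fixed before the data were examined, with edgeR's quasi-likelihood test as the main test; because the files hold CPM, limma was used as the main test and edgeR on the recovered reads became an alternative, which called 161 genes. Low genes were removed with filterByExpr on the recovered reads (minimum count 10), leaving 10324 genes. CPM were divided by TMM factors, which lay between 0.964 and 1.06, and log2(CPM + 1) was fitted with limma (lmFit, and eBayes with a mean trend) on the group alone. Fold changes are on that log2 scale with a pseudocount of 1 CPM and understate the change of low genes; printed CPM are the deposited ones, with mean ± SD over n = 2 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Calls given without a setting are those of this main fit. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

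Before the data were examined, 32 gene lists were fixed, and the 26 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; no gene of the list of mitochondrially encoded genes was matched. Camera called 17 lists (18 at an unadjusted p under 0.05). With camera's estimated correlation for each list 0 lists were called (4 at an unadjusted p under 0.05). That setting also uses the residual degrees of freedom of only 4 libraries, so it had little power here. Its estimate was -0.0236 for the cytokine list, below the preset value, 0.474 for the glycolysis list and 0.721 for the ribosomal protein list. A call lost with it does not by itself point to correlated genes. Where the estimate lies far above the preset value, camera's p at the preset value may be too small. Limma's fry called 3 lists, those of Th17-associated genes, of cytokines, and of JAK-STAT and SOCS genes. Genes were named by a rule fixed at the same time: Il9, Batf, Batf3, Tnfrsf25, Tnfsf15, Irf4 and Spi1 in every case; the 10 called genes higher and the 10 lower with the smallest p and non-overlapping groups, skipping predicted models; and for each list up to 3 called members with the largest absolute log2 fold change, or, with none called, its most abundant member. List members named beyond that rule, and genes outside the lists, were chosen after their values were seen. Counts adjusted over a list alone are not corrected across the lists and do not test enrichment. Of all 10324 tested genes, 1722 had an unadjusted limma p under 0.05.

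The tests were checked on simulated data made from these libraries' means, sizes and edgeR gene-wise dispersions, with 200 changed genes in each of 5 runs on 10068 genes. For this comparison limma recovered 36.5% of genes changed 2-fold and 76.9% of those changed 4-fold, with 5.80 false calls per run. Genes were drawn independently and without a trend with transcript length or GC content, so false calls in the real data may be more frequent. Replicates were not copies of one library, since their counts differed by 12.7 (Th9) and 7.67 (TL1A) times sampling noise as chi-square per degree of freedom. Alternatives were other scaling (RLE, upper quartile, total count), no or a stricter filter, DESeq2, edgeR's exact, robust and legacy quasi-likelihood tests and limma voom on recovered reads, the replicate number as a block, a test against a 1.5-fold change (run in limma as well), and leaving out each library. EdgeR's quasi-likelihood test and camera on the edgeR fit had been fixed beforehand as the main tests for counts. Limma and camera on the log2 CPM replaced them once the files were found to hold CPM, and both edgeR tests were run on recovered reads as alternatives. Chosen after seeing the data were pseudocounts of 0.5 and 3 CPM, total count scaling for the lists, and removal of each library's trend with transcript length and GC content. The trend was a lowess with a span of 0.3 on each library's deviation from the gene mean. Length and GC content came from the GENCODE M21 transcripts, with a value for 98.3% of tested genes.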

Results

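RNA of mouse T cells was sequenced in 4 libraries, 2 from cells cultured under Th9 conditions and 2 from cells cultured under Th9 conditions with TL1A. Th9 cells are helper T cells known for making interleukin 9, and TL1A is a cytokine of the TNF superfamily whose receptor is encoded by Tnfrsf25. The reads counted in genes came to 4041633 and 3167270 in the Th9 libraries and 2979482 and 3081187 in the TL1A libraries, and between 12122 and 12534 genes had at least 1 read. A count of 3 reads corresponded to 0.742 to 1.01 CPM, which bounds what a value of 0 can hide, for counting error only. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

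The comparison asked how the transcriptome of Th9 cells differed when TL1A was present (n = 2 libraries per group). With TL1A, Il9, the gene of interleukin 9, rose 1.97-fold, and the cytokine genes Il21, Il24 and Il17f rose 9.97-fold, 4.95-fold and 8.89-fold. Gatm, which encodes the first enzyme of creatine synthesis, rose 6.01-fold. Foxp3, the lineage factor of regulatory T cells, fell 4.29-fold, and Gzmb, which encodes the protease granzyme B, fell 3.17-fold. Of these genes only Gatm and Il24 kept their call whichever library was left out. Among 10324 genes tested with limma, 118 changed at an adjusted p under the threshold of 0.05, 92 of them higher and 26 lower with TL1A. Of the 118, 106 changed by more than 2-fold. The count was 42 without Th9 replicate 1 and 19 without Th9 replicate 2. The lower genes numbered 3, 0, 68 and 46 without Th9 replicate 1, Th9 replicate 2, TL1A replicate 1 and TL1A replicate 2. The higher genes numbered 39, 19, 87 and 50 in the same order. The groups did not overlap in 48.1% of tested genes, where chance gives 33.3% for 2 against 2.

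**Figure D1:**
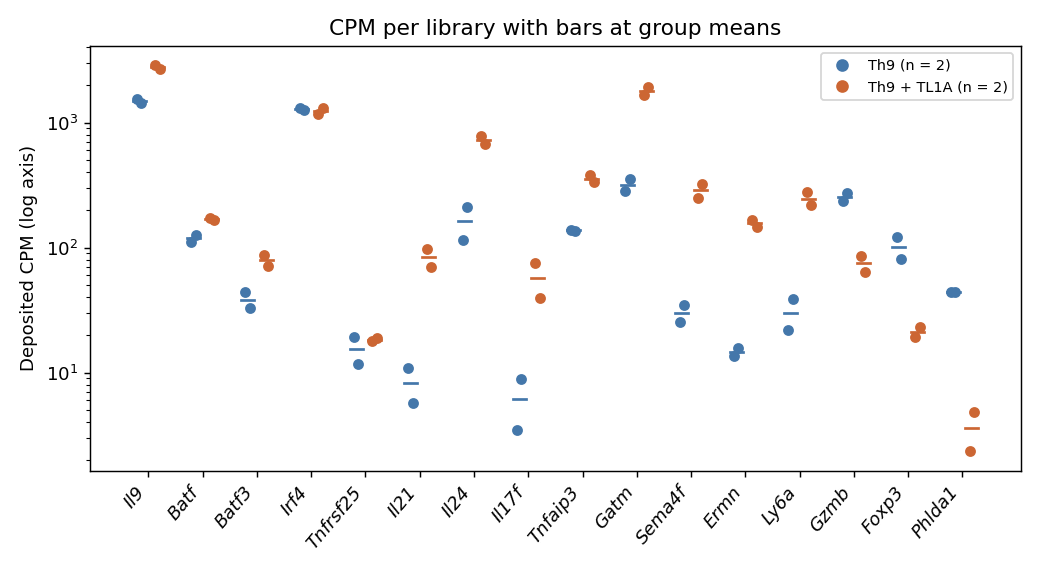
Deposited CPM on a log axis for 16 genes in each library, blue for Th9 and orange for Th9 with TL1A, with 2 points per group and a bar at the group mean. Il9 lay at 1559.8 and 1445 CPM in the Th9 libraries and at 2879 and 2683 CPM in the TL1A libraries, and Foxp3 at 123 and 80.5 against 19.1 and 23.0.

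Il9 (Entrez 16198, chromosome 13, 56479277 to 56482257 of mm10) rose from 1503 ± 80.9 to 2781 ± 138 CPM (SD, n = 2 per group), a log2 fold change of 0.98 ± 0.18 (SE, adjusted p = 0.0261, limma). Its call was lost without Th9 replicate 2 (adjusted p = 0.0734), without TL1A replicate 1 (0.215) and without TL1A replicate 2 (0.191), while its log2 fold change stayed between 0.92 and 1.04. Batf3 (Entrez 381319, chromosome 1, 191098414 to 191108943), a transcription factor of the AP-1 family named in the series title, had 38.4 ± 7.92 CPM without and 79.7 ± 11.2 CPM with TL1A. Its log2 fold change of 1.13 ± 0.27 did not pass the test (limma adjusted p = 0.0722). Batf (Entrez 53314, chromosome 12, 85686720 to 85709087), the related factor also named there, had 119 ± 10.2 and 169 ± 4.01 CPM. Its log2 fold change of 0.60 ± 0.20 did not pass either (adjusted p = 0.165). Irf4, a partner of BATF on DNA, had 1281 ± 42.7 and 1239 ± 95 CPM (adjusted p = 0.941). Tnfrsf25, the TL1A receptor gene, had 15.5 ± 5.39 and 18.3 ± 0.732 CPM (adjusted p = 0.738). Tnfsf15, which encodes TL1A itself, had 0 reads in the Th9 libraries and 0.336 and 0.974 CPM in the TL1A libraries, at or under the floor of 3 reads. Spi1, which encodes PU.1, had 0 reads in all 4 libraries. Of the 26 tested genes in the list of Th9 cytokine and regulators, Il9 and Il21 rose, and adjusted over the list alone 8 were higher and 1 lower. Batf, Batf3, Ccl17, Ccl22, Il10 and Foxo1 were the others among the higher, and Tgfbr1 was the lower. As a set the list was higher than other genes (camera adjusted p = 1.47e-04; adjusted p = 0.287 with an estimated correlation).

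The 10 genes with the smallest p among those higher with TL1A were Gatm, Sema4f, Ermn, Ly6a, Il1rn, Alpk2, Slamf1, Cd200, Rnh1 and Timp1. Gatm (Entrez 67092, chromosome 2, 122594473 to 122611277) rose from 318 ± 49.6 to 1790.0 ± 175 CPM (log2 fold change 2.59 ± 0.19 SE, limma adjusted p = 9.88e-05). Sema4f, which encodes a semaphorin, rose from 30.0 ± 6.71 to 287 ± 53.2 CPM, and Ermn from 14.7 ± 1.54 to 158 ± 14.5 CPM. Ly6a, which encodes the surface protein Sca-1, rose from 30.1 ± 11.8 to 247 ± 41.8 CPM. Il1rn, which encodes the interleukin 1 receptor antagonist, rose from 44.1 ± 4.22 to 200.4 ± 8.02 CPM, and Slamf1, a lymphocyte surface receptor gene, from 93.3 ± 1.07 to 288 ± 12 CPM. Alpk2, Cd200 and Rnh1, the gene of the ribonuclease inhibitor, had log2 fold changes of 2.55, 1.88 and 1.69. Timp1, which encodes an inhibitor of metalloproteinases, rose from 3.82 ± 0.851 to 77.5 ± 37.5 CPM, but its locus overlaps Syn1, and the kit does not mark strand. Without Th9 replicate 2, Slamf1 (adjusted p = 0.0596), Cd200 (0.0791) and Timp1 (0.0826) lost their calls. Gatm, Sema4f, Ermn, Ly6a, Il1rn, Alpk2, Rnh1 and Il24 were the 8 of 45 named called genes that kept their call whichever library was left out. In all, 23, 12, 38 and 28 of the 45 stayed called without Th9 replicate 1, Th9 replicate 2, TL1A replicate 1 and TL1A replicate 2. Without a filter on low counts 23 of the 45 lost their call, namely Phlda1, Satb1, Nr4a2, Il17f, Rif1, Socs3, Scd1, Cd5, Tgtp2, Il18r1, Il9, Jak2, Il1r1, Btla, Tnfsf8, Il12rb2, Pim2, Foxp1, Cd83, Fas, Edem1, Ctla2a and Mki67. With total count scaling 11 did, namely Il1r1, Btla, Tnfsf8, Il12rb2, Pim2, Foxp1, Cd83, Fas, Edem1, Ctla2a and Mki67.

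Among genes lower with TL1A, the 10 with the smallest p were Gzmb, Hmgn2, Foxp3, Tbc1d4, Phlda1, Tgtp1, Dnah7a, Itih5, Rif1 and Serpina3g. Gzmb (Entrez 14939, chromosome 14, 56258836 to 56262334) fell from 254 ± 24.4 to 75.3 ± 15.6 CPM (log2 fold change -1.66 ± 0.22 SE, limma adjusted p = 0.00427). Foxp3 (Entrez 20371, chromosome X, 7579676 to 7595243) fell from 102 ± 29.8 to 21.1 ± 2.77 CPM (log2 fold change -2.10 ± 0.29, adjusted p = 0.00617); its locus overlaps Ccdc22 and Flicr. Phlda1 fell from 44.0 ± 0.110 to 3.61 ± 1.78 CPM, Hmgn2, a nucleosome-binding protein gene, from 299 ± 43.3 to 99.6 ± 17.9 CPM, and Tbc1d4, a Rab GTPase-activating protein gene, from 151 ± 48.1 to 38.4 ± 7.72 CPM. Rif1, which encodes a protein of DNA repair and replication timing, Itih5 and Serpina3g had log2 fold changes of -1.46, -2.05 and -1.67. Tgtp1 fell from 155 ± 50.5 to 45.2 ± 2.94 CPM, and its near copy Tgtp2 from 129 ± 55.6 to 35.5 ± 6.21 CPM, and how their shared reads were counted is not given in the sources used here. Dnah7a, a dynein heavy chain gene with the close relative Dnah7b, had 98 and 53 reads in the Th9 libraries and 0 in both TL1A libraries, which makes it at least 20.7-fold lower against a floor of 3 reads per library. No gene was called lower without Th9 replicate 2, where the adjusted p was 0.120 for Gzmb, 0.0912 for Foxp3, 0.0912 for Hmgn2, 0.0912 for Tbc1d4, 0.139 for Phlda1, 0.0866 for Tgtp1, 0.120 for Dnah7a, 0.133 for Itih5, 0.121 for Rif1 and 0.141 for Serpina3g. Without Th9 replicate 1 Gzmb (0.0152) and Hmgn2 (0.0426) kept their calls, and the others did not, with 0.0804 for Foxp3 and 0.0804 for Phlda1. Tgtp2 was not called without Th9 replicate 1 (adjusted p = 0.217), Th9 replicate 2 (0.0912) or TL1A replicate 2 (0.0594).

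**Figure D2:**
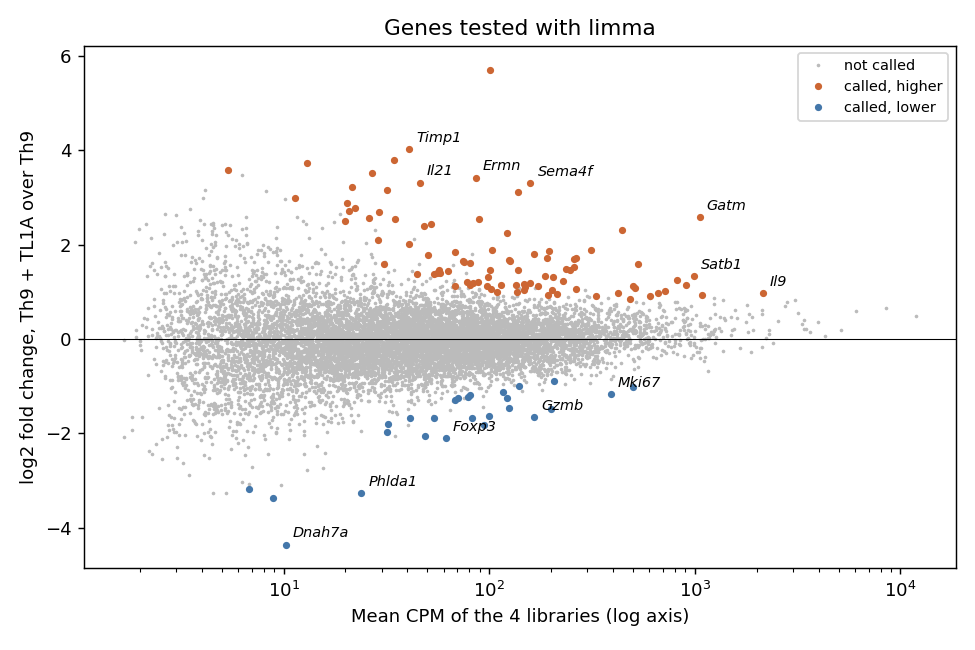
The log2 fold change of Th9 with TL1A over Th9 for each of the 10324 tested genes, plotted against the mean CPM of the 4 libraries on a log axis. The 92 genes called higher are orange, the 26 called lower are blue and all others are grey, and Gatm lies at a log2 fold change of 2.59.

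Genes associated with Th17 cells formed the list furthest above other genes. Of its 14 tested members, Il17f, Il21, Il1r1, Ahr, Tmem176a and Tmem176b rose, 6 in all, and none fell. Adjusted over the list alone 10 were higher, Rora, Il22 and Hif1a among them. Il21 rose from 8.28 ± 3.68 to 83.7 ± 19.3 CPM, Il17f from 6.15 ± 3.80 to 57.6 ± 25.4 CPM and Il1r1, an interleukin 1 receptor gene, from 1.42 ± 2.01 to 24.5 ± 6.19 CPM. Ahr, which encodes a ligand-activated transcription factor, had a log2 fold change of 1.80 ± 0.25 (SE, limma adjusted p = 0.00558). Without Th9 replicate 2 Il21 (adjusted p = 0.0791), Il17f (0.0912), Il1r1 (0.0866), Ahr (0.05002), Tmem176a (0.0866) and Tmem176b (0.131) lost their calls. Il1r1 (0.0804) and Tmem176a (0.0572) also lost theirs without Th9 replicate 1, and Il1r1 without TL1A replicate 2 (0.121). Il22 had 0 reads in both Th9 libraries and 20.5 and 4.54 CPM in the TL1A libraries, at least 14.8-fold higher against a floor of 3 reads per library, and did not pass over all genes (adjusted p = 0.0789). That bound was 5.38-fold without TL1A replicate 1 and 24.2-fold without TL1A replicate 2. The median log2 fold change of the list was 1.47, with Il22 at its fitted value or at its bound (camera adjusted p = 4.10e-11; adjusted p = 0.287 with an estimated correlation). In the list of cytokines, Il9, Il17f, Il21 and Il24 rose among 26 tested genes. Each of these is also counted in the Th9, Th17-associated or Th2-associated list, so the cytokine set is not independent of those. Adjusted over the cytokine list alone 12 were higher and 0 lower, Il4, Il5, Il10 and Il13 among them. Its median was 1.0, with Il22 at its fitted value or at its bound, and 0.60 without TL1A replicate 1 and 0.50 without a filter on low counts (camera adjusted p = 2.15e-09; adjusted p = 0.287 with an estimated correlation).

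Lists for other helper T cell types held fewer called genes in the main fit, a difference that was not tested. Of 13 tested Th1-associated genes, Il12rb2 and Il18r1, which encode receptor chains for interleukins 12 and 18, rose to 388 ± 55.9 and 34.1 ± 8.28 CPM from 137 ± 82.6 and 5.54 ± 1.54, and 4 were higher adjusted over the list alone (camera adjusted p = 2.93e-05; adjusted p = 0.287 with an estimated correlation). The locus of Il12rb2 overlaps Serbp1, and its call was lost without Th9 replicate 1 (adjusted p = 0.0572). Il18r1 was not called without Th9 replicate 1 (adjusted p = 0.0951), Th9 replicate 2 (0.120), TL1A replicate 1 (0.0746) or TL1A replicate 2 (0.0594). Tbx21, which encodes the Th1 lineage factor T-bet, had 7.73 ± 6.91 and 10.4 ± 2.32 CPM (adjusted p = 0.625), and Ifng, below the filter on low counts, had 7 and 12 reads in the Th9 libraries and 0 in both TL1A libraries, at least 2.79-fold lower against a floor of 3 reads per library (1.75-fold without Th9 replicate 2). Of 15 tested Th2-associated genes Il24 rose, from 162 ± 68.1 to 727 ± 68.4 CPM, and 2 were higher adjusted over the list alone, Il13 being the other (camera adjusted p = 0.00502; adjusted p = 0.417 with an estimated correlation). The Th2 set was not called without Th9 replicate 1 (adjusted p = 0.0776). Gata3, the Th2 lineage factor, had 308 ± 42.0 and 259 ± 18.6 CPM (adjusted p = 0.752). Of 17 tested Treg-associated genes, Foxp3 fell and Cd83 rose, and adjusted over the list alone 5 were higher and 4 lower. The set was not called (camera adjusted p = 0.762). Foxp3 was not called without Th9 replicate 1 (adjusted p = 0.0804) or Th9 replicate 2 (0.0912), and Cd83 was not called whichever of the 4 libraries was left out (adjusted p between 0.0782 and 0.268). Ctla4 had 551 ± 81.0 and 532 ± 173 CPM and Il2ra 3057 ± 113 and 3581 ± 24.8 CPM, neither past the test. Gzmb was the 1 called gene of 8 tested cytotoxic effectors, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.567). Gzmb was not called without Th9 replicate 2 (adjusted p = 0.120).

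Some genes of several signalling pathways rose. In the list of NF-kB pathway and targets, Tnfaip3, which encodes the feedback inhibitor A20, rose from 137 ± 0.956 to 356 ± 30.9 CPM and Cd83, a surface molecule of activated lymphocytes, from 358 ± 7.86 to 611 ± 78.2 CPM. Of 43 tested genes, 11 were higher and 1 lower adjusted over the list alone, including Nfkbia, Bcl3, Traf1, Birc3 and Icam1. The set was called (camera adjusted p = 0.00167; adjusted p = 0.360 with an estimated correlation), but not without Th9 replicate 2 (adjusted p = 0.0537), where Tnfaip3 was not called either (0.0772). Among 25 tested TNF superfamily ligands and receptors, Fas and Tnfsf8, which encodes the CD30 ligand, rose to 91.9 ± 2.72 and 82.6 ± 15.8 CPM from 44.1 ± 1.26 and 32.6 ± 6.77, and 4 were higher adjusted over the list alone. That set was called (camera adjusted p = 0.0282; adjusted p = 0.360 with an estimated correlation), but not without Th9 replicate 1 (adjusted p = 0.0538) or with the length and GC trend removed (0.151). Fas and Tnfsf8 were not called without Th9 replicate 1 (adjusted p = 0.178 and 0.0785), Th9 replicate 2 (0.153 and 0.178) or TL1A replicate 2 (0.143 and 0.153), nor Fas without TL1A replicate 1 (0.0746). Among 24 tested JAK-STAT and SOCS genes, Socs3, Pim2 and Jak2 rose with log2 fold changes of 1.49, 0.97 and 0.93, and 6 were higher adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.360 with an estimated correlation). Socs3 was not called without TL1A replicate 2 (adjusted p = 0.0533) and Jak2 without Th9 replicate 2 (0.0772), TL1A replicate 1 (0.0875) or TL1A replicate 2 (0.198). Pim2 was not called without Th9 replicate 1 (adjusted p = 0.129), Th9 replicate 2 (0.0956), TL1A replicate 1 (0.140) or TL1A replicate 2 (0.0776). Among 18 tested TGF-beta response genes Ctla2a rose from 468 ± 119 to 857 ± 49.0 CPM, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.360 with an estimated correlation). Ctla2a was not called without Th9 replicate 1 (adjusted p = 0.0828), Th9 replicate 2 (0.0596) or TL1A replicate 2 (0.180).

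Of 25 tested T cell activation and inhibitory receptors, Cd200, Nr4a2, Btla and Cd5 rose, with log2 fold changes of 1.88, 2.55, 1.15 and 1.13, and adjusted over the list alone 5 were higher and 3 lower. Cd28 was the other higher gene, and Egr1, Nr4a3 and Cd96 were the lower. The set was called (camera adjusted p = 0.0422; adjusted p = 0.360 with an estimated correlation), but not without Th9 replicate 2 (adjusted p = 0.310) or TL1A replicate 1 (0.104). Without Th9 replicate 2 the adjusted p was 0.0791 for Cd200, 0.125 for Nr4a2, 0.175 for Btla and 0.120 for Cd5. Btla was also not called without Th9 replicate 1 (adjusted p = 0.0572) or TL1A replicate 2 (0.144), nor Cd5 without Th9 replicate 1 (0.0928) or TL1A replicate 1 (0.0633). In the list of naive and memory T cell genes, Satb1, which encodes a chromatin organiser, rose from 593 ± 132 to 1381 ± 51.0 CPM, and Foxp1, a forkhead factor gene, fell from 191 ± 36.8 to 88.6 ± 2.34 CPM. Of its 20 tested genes, 5 were higher and 1 lower adjusted over the list alone. Satb1 was not called without TL1A replicate 2 (adjusted p = 0.0533), nor Foxp1 without Th9 replicate 1 (0.264), Th9 replicate 2 (0.123) or TL1A replicate 2 (0.129). Foxp1 lost its call with the length and GC trend removed (log2 fold change -0.996 ± 0.20 before and -0.82 ± 0.20 after, adjusted p = 0.0693). The set was called (camera adjusted p = 0.0480; adjusted p = 0.360 with an estimated correlation), but not without Th9 replicate 2 (adjusted p = 0.0515) or TL1A replicate 1 (0.183). Of 8 tested chemokines and chemokine receptors none was called over all genes in the main limma fit. Adjusted over the list alone, Ccl17, Ccl22 and Ccr7 were higher, Ccr7 having 531 ± 70.4 and 824 ± 164 CPM. That set was called (camera adjusted p = 0.00771; adjusted p = 0.360 with an estimated correlation), but not without Th9 replicate 1 (adjusted p = 0.0767), TL1A replicate 1 (0.309) or TL1A replicate 2 (0.0735).

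As sets, cell cycle genes were lower with TL1A, and genes of ribosomal proteins and glycolysis higher, by camera. With an estimated correlation the adjusted p was 0.360 for the cell cycle list and 0.417 for both others. By fry none of these sets was called, with an adjusted p of 0.0804 for cell cycle, 0.241 for ribosomal proteins and 0.272 for glycolysis. Of 43 tested cell cycle genes Mki67, the proliferation marker Ki-67, fell from 555 ± 235 to 223 ± 37.4 CPM. Adjusted over the list alone 8 were lower, among them Mcm2, Rrm2, Ccna2 and Bub1, and 2 higher, Ccnd2 and Cdkn1a. Mki67 was not called without Th9 replicate 1 (adjusted p = 0.216), Th9 replicate 2 (0.0803) or TL1A replicate 2 (0.0669). The median log2 fold change was -0.41 (camera adjusted p = 3.79e-07; adjusted p = 0.360 with an estimated correlation). None of 25 tested ribosomal protein genes was called by limma, and 0 were past the threshold adjusted over the list alone. Their median was 0.35, with 0.22 without Th9 replicate 1 and 0.54 without Th9 replicate 2 (camera adjusted p = 1.92e-07; adjusted p = 0.417 with an estimated correlation). Rps3 had 2185 ± 276 and 3312 ± 161 CPM. None of 24 tested glycolysis genes was called, while Slc2a3 and Aldoc were higher and Pdk1 lower adjusted over the list alone. The median was 0.32 (camera adjusted p = 5.23e-05; adjusted p = 0.417 with an estimated correlation). Summed over the glycolysis list, CPM were 23999.7 and 30733.7 in Th9 replicates 1 and 2 and 32799 and 32518 with TL1A, and the median without Th9 replicate 1 was 0.18 (camera adjusted p = 0.00464). Pkm, the most abundant of them, had 4976 ± 882 and 5316 ± 221 CPM (adjusted p = 0.718). Across 10148 genes, which are not independent replicates, log2 fold changes fell with transcript length (Spearman rho -0.172) and rose with GC content (0.151). The difference of TL1A replicate 1 from TL1A replicate 2 also fell with length (-0.161), and that of Th9 replicate 1 from Th9 replicate 2 rose with it (0.0789). The median transcript length was 1128 nucleotides for the ribosomal protein list, 3228 for glycolysis and 3398 for cell cycle. With that trend removed, Il9 had a log2 fold change of 0.80 ± 0.18 and Mki67 of -0.93 ± 0.21, both with an adjusted p of 0.0523, and Ctla2a of 0.90 ± 0.20 (adjusted p = 0.0501). These calls ended as the fold changes moved toward 0 relative to their SE, from 0.98 ± 0.18, -1.16 ± 0.25 and 0.99 ± 0.21.

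**Figure D3:**
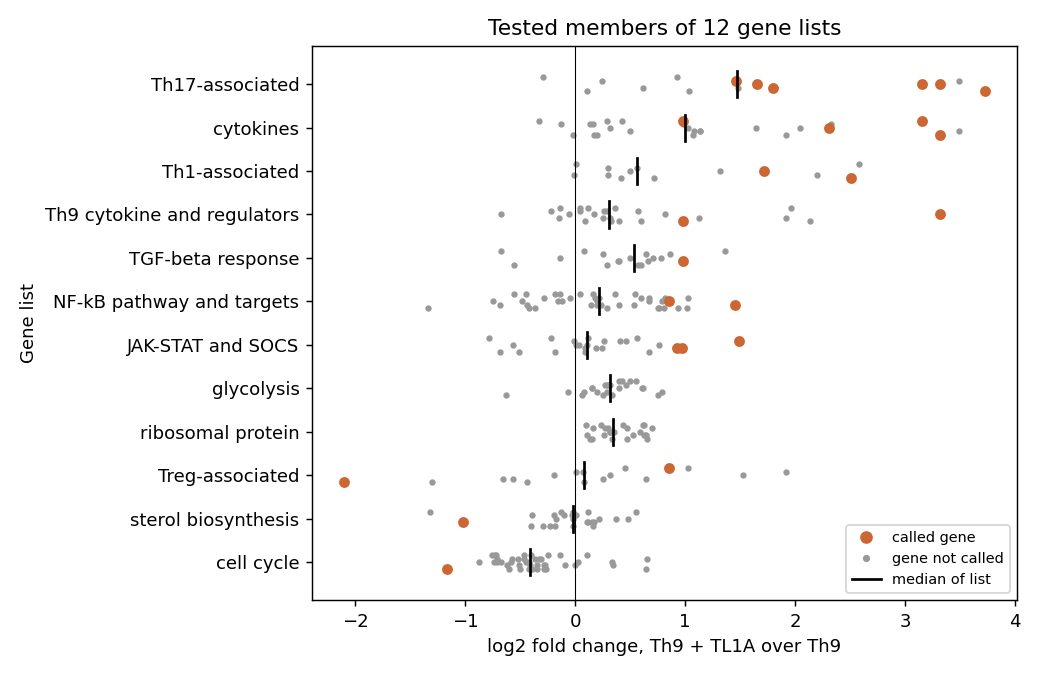
The log2 fold change of Th9 with TL1A over Th9 for the tested members of 12 gene lists, with called genes in orange, others in grey and a black line at each list's median. The median of the Th17-associated list lies at 1.47 and that of the cell cycle list at -0.41.

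None of the remaining pathway and factor lists was called as a set by camera. Of 27 tested interferon-stimulated genes Gbp2, a guanylate-binding protein gene, rose from 75.3 ± 1.14 to 199 ± 44.6 CPM while Tgtp1 and Tgtp2 fell, and adjusted over the list alone 4 were higher and 2 lower (camera adjusted p = 0.674). Gbp2 was not called without Th9 replicate 2 (adjusted p = 0.120), nor Tgtp1 and Tgtp2 without Th9 replicate 1 (0.112 and 0.217) or Th9 replicate 2 (0.0866 and 0.0912), and Tgtp2 also not without TL1A replicate 2 (0.0594). The sterol biosynthesis list also holds genes of fatty acid metabolism, among them Acaca and Scd1, which encodes a fatty acid desaturase. Of its 26 tested genes Scd1 fell from 683 ± 60.6 to 316 ± 33.2 CPM. Acaca joined it adjusted over the list alone, with 0 higher (camera adjusted p = 0.479). Scd1 was not called without Th9 replicate 2 (adjusted p = 0.104) or TL1A replicate 2 (0.143). Of 25 tested genes of the unfolded protein and amino acid stress response Edem1, a gene of endoplasmic reticulum protein degradation, rose from 499 ± 140.2 to 935 ± 25.9 CPM. With Atf3, 2 were higher adjusted over the list alone (camera adjusted p = 0.887, direction higher), while the list's median log2 fold change was -0.02 and its mean 0.04. The camera direction was lower with total count scaling, with the length and GC trend removed and without Th9 replicate 1. Edem1 was not called without Th9 replicate 1 (adjusted p = 0.0661) or TL1A replicate 2 (0.159). No gene was called in the main limma fit among 27 tested bZIP transcription factors (camera adjusted p = 0.154), 8 interferon regulatory factors (0.900) and 27 genes of the BCL2 family and caspases (0.741). With upper quartile or total count scaling, a pseudocount of 3 CPM or the length and GC trend removed, limma called 1 interferon regulatory factor lower. Limma voom, DESeq2 and edgeR's exact, robust and quasi-likelihood tests on recovered reads also called 1 interferon regulatory factor lower. With the replicate block limma called 1 bZIP factor higher. DESeq2 called 1 bZIP factor higher and edgeR's exact test 2. Adjusted over the list alone, Batf3 was higher among the bZIP factors, Irf5 higher and Irf8 lower among the interferon regulatory factors, and 0 genes passed in the BCL2 list. Xbp1 had 622 ± 19.0 and 491 ± 16.5 CPM and Mcl1 487 ± 17.6 and 583 ± 2.18 CPM.

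Markers of T cells were abundant and those of most other cell types near 0. Cd4 had 464 ± 8.97 and 500.0 ± 28.7 CPM and Cd3e 145 ± 14.7 and 129.9 ± 4.72 CPM. Of 11 tested pan T cell markers Cd5, which encodes an inhibitory receptor, rose from 112 ± 4.78 to 233 ± 33.5 CPM and was the 1 gene past the threshold adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.360 with an estimated correlation). Cd5 was not called without Th9 replicate 1 (adjusted p = 0.0928), Th9 replicate 2 (0.120) or TL1A replicate 1 (0.0633). Of 5 tested B cell markers none was called over all genes by limma and Cd79b and Ebf1 were higher adjusted over the list alone, with 9.57 ± 4.78 and 26.4 ± 3.11 CPM for Cd79b (camera adjusted p = 0.0288; adjusted p = 0.360 with an estimated correlation). The B cell set was not called without Th9 replicate 1 (adjusted p = 0.0665), Th9 replicate 2 (0.0683) or TL1A replicate 1 (0.0866). Of 5 tested macrophage and dendritic cell markers none was called and H2-Ab1 was higher adjusted over the list alone (camera adjusted p = 0.0714); this set was called without Th9 replicate 2 (adjusted p = 0.0327) and without TL1A replicate 2 (0.0372). Cd74 had 157 ± 30.3 and 161 ± 34.2 CPM. Cxcr2 was the 1 tested neutrophil marker, with 0.789 ± 1.12 and 8.31 ± 4.86 CPM, and Cd8b1 the 1 tested CD8 T cell marker, with 9.97 ± 4.65 and 9.56 ± 0.706 CPM. Kit, the 1 tested marker of mast cells, basophils and ILC2, had 2.53 ± 3.57 and 2.52 ± 3.56 CPM. No marker of NK and innate-like T cells or of erythroid cells and platelets was abundant enough to test; Klrd1 had 2.23 and 1.89 CPM in the Th9 and 1.01 and 0.974 CPM in the TL1A libraries.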

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

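The pseudocounts of 0.5 and 3, total count scaling for the lists and the removal of the length and GC trend were chosen after the data were seen. EdgeR's quasi-likelihood test and camera on the edgeR fit were the tests fixed beforehand, and were run on recovered reads as alternatives. All 118 called genes kept their sign under each alternative. This could hardly have come out otherwise, since the groups did not overlap in any of the 118. Each named gene other than Il9, Batf and Batf3, and each gene list, was counted once per alternative. Of these results 208 lost a call, 7 gained one and 1269 stayed on their side of the threshold. The 1269 include results called neither in the main test nor in the alternative. Against 118 genes called (92 higher, 26 lower), total count scaling gave 73 (52 and 21; median log2 fold change of all genes -0.10 against -0.01), no filter on low counts 33 (25 and 8), DESeq2 275 (185 and 90; adjusted p not given for 1802 genes), edgeR's exact test 485 (290 and 195), edgeR's robust test 158 (117 and 41), its quasi-likelihood test 161 (117 and 44) and upper quartile scaling 153 (110 and 43). The test against a 1.5-fold change gave 20 (18 and 2), by construction a smaller count. Of 45 named called genes 31 lost their call in that test, 8 in the edgeR fit with a replicate block, 6 in edgeR's legacy test, 4 with the trend removed, 2 in DESeq2, 2 with a pseudocount of 0.5 and 1 in limma voom. With 1 library left out, where the lone library of a group is assumed to vary like the other group, the count lay between 19 and 155, with 19 to 87 higher and 0 to 68 lower; each such fit has fewer libraries. With the trend removed 139 were called, 113 of them among the 118. Il9 was not called without a filter (log2 fold change 0.98, adjusted p = 0.117), in the 1.5-fold test (0.98) or with the trend removed (0.80 and 0.0523); its range over 21 alternatives was 0.80 to 1.04 (0.92 to 1.04 with 1 library left out), and 14 passed the threshold. Batf3 was called by DESeq2 (log2 fold change 1.15, adjusted p = 0.0224) and edgeR's exact test (1.14 and 0.00675), with a range of 0.88 to 1.29; Batf passed under none of 21 (0.39 to 0.74). Of 17 lists called by camera, 0 were called with an estimated correlation. Limma's fry called 3, the Th17-associated list, the cytokine list and the JAK-STAT and SOCS list. Camera on the edgeR fit called 17. Without a filter the chemokine (adjusted p = 0.536), activation (0.145) and B cell (0.135) sets were not called. For other counts and calls that changed, the cause was not tested. In simulated data with these library sizes and 2 libraries per group, 36.5% of genes changed 2-fold were recovered; depth was not varied.

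With the replicate number as a block 225 genes were called (147 higher, 78 lower) by limma, against 118 without it, and 125 (92 and 33) by edgeR's quasi-likelihood test, against 161. With the block, limma called Batf3 (log2 fold change 1.13, adjusted p = 0.0363) and Il9 (adjusted p = 0.0400), and edgeR called neither Batf3 (adjusted p = 0.0666) nor Il9 (0.98 and 0.0829). Camera with the block, run on the limma values, called 17 lists. Same-numbered libraries did not deviate together (correlation of deviations -0.0110), and no label says that a number marks a shared animal, batch or day, so the numbers were not taken to pair the samples. The names of the deposited files give both libraries numbered 2 the same unexplained tag.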

Other observations

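The removal of the length and GC trend was chosen after the data were seen, and the tests of a single library as the cause were chosen after the result was seen. The genes that follow were chosen after their values were seen, and the families were put together around called genes and not tested for enrichment. Of 7 tested genes for interleukin 1 and interleukin 18 receptors and their antagonist, Il1r1, Il1r2, Il1rn and Il18r1 rose and 0 fell, of which Il1r1 is also counted in the Th17-associated list and Il18r1 in the Th1-associated list. Il1r2, which encodes the decoy receptor, rose from 5.27 ± 3.26 to 36.3 ± 12.9 CPM (SD, n = 2 per group). Without 1 library the adjusted p of Il1r2 reached 0.148 (TL1A replicate 2), 0.117 (Th9 replicate 1) and 0.109 (Th9 replicate 2). Both tested cysteinyl leukotriene receptor genes rose, Cysltr1 from 48.6 ± 1.86 to 108 ± 14.9 CPM and Cysltr2 from 4.91 ± 0.646 to 39.7 ± 19.8 CPM. Of 8 tested integrin alpha chain genes Itga3 and Itga7 rose, with log2 fold changes of 2.88 and 1.23, and of 6 tested SLAM family genes Slamf1 and Slamf7 rose (1.71 and 1.19). Of the nuclear lamin genes Lmna rose from 15.6 ± 2.08 to 81.0 ± 9.39 CPM and Lmnb1 fell from 163 ± 5.65 to 69.8 ± 2.31 CPM, while Lmnb2, the other of 3 tested, was not called. Enpp2, which encodes autotaxin, had 0 and 13.9 CPM in the Th9 libraries and 201 and 189 CPM with TL1A (adjusted p = 0.010, limma). Pcsk1, which encodes a prohormone convertase, had 0 reads in both Th9 libraries and 31 and 34 reads with TL1A, at least 12.7-fold higher against a floor of 3 reads per library. Inhba, an activin subunit gene, rose from 11.1 ± 3.48 to 46.7 ± 0.0586 CPM, and Axl, a receptor kinase gene, from 109.9 ± 11.2 to 263 ± 33.2 CPM. Without Th9 replicate 2 Enpp2 kept its call (0.0138), and these genes lost theirs: Cysltr1 (adjusted p = 0.133), Cysltr2 (0.136), Itga3 (0.102), Itga7 (0.0616), Slamf1 (0.0596), Slamf7 (0.0902), Lmna (0.0791), Lmnb1 (0.161), Pcsk1 (0.131), Inhba (0.105) and Axl (0.0866). Without Th9 replicate 1 this held for Cysltr1 (0.163), Cysltr2 (0.0754), Itga3 (0.0504), Itga7 (0.112), Slamf7 (0.0910), Lmnb1 (0.0951), Pcsk1 (0.166) and Inhba (0.105). Without TL1A replicate 1 Cysltr2 (0.0974) and Pcsk1 (0.237) were not called, and without TL1A replicate 2 Cysltr1 (0.143), Itga7 (0.0812), Slamf7 (0.0594), Lmnb1 (0.0698), Pcsk1 (0.161), Inhba (0.0851) and Axl (0.0575). H2-Ab1 had between 83.9 and 146 CPM in the 4 libraries, while its partner chain H2-Aa reached at most 0.325 CPM and Lyz2, Ms4a1, Tyrobp and Fcer1g had 0 reads.

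The cell cycle list lay lower with TL1A, by a median log2 fold change of -0.41. A trend with transcript length and GC content is argued against as its whole cause, since the list lay close to all tested genes in both. Its median length was 3398 nucleotides and its GC content 48.7%, against 3376.5 and 49.4% over all tested genes. Removing the trend could thus hardly have ended the shift. After it the median was -0.38 (bootstrap interval over genes taken as independent -0.51 to -0.29) and the camera adjusted p 3.86e-07, although Mki67 itself lost its call. A single library is argued against as well, because the highest adjusted p with 1 library left out was 4.41e-05. An effect of TL1A stays open as an untested explanation. The list was not called with an estimated correlation (camera adjusted p = 0.360) or by fry (adjusted p = 0.0804).

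The ribosomal protein list lay higher with TL1A, by a median log2 fold change of 0.35, but the set was not called with an estimated correlation (adjusted p = 0.417), which was 0.721 between its genes. Whether a single library was the whole cause could not be decided. The list's summed CPM were 14557 and 17568 in Th9 replicates 1 and 2, and 20958 and 19625 in TL1A replicates 1 and 2. The median was 0.22 without Th9 replicate 1 and 0.54 without Th9 replicate 2, and the direction stayed higher whichever library was left out. The highest camera adjusted p with 1 library left out was 3.03e-04, at the preset correlation of 0.01. With an estimate of 0.721 between these genes, that p may be too small to decide it. The length and GC trend could account for part of the rise. After its removal the median was 0.197, between the bounds of 0.1 and 0.2 set beforehand (bootstrap interval over genes taken as independent 0.16 to 0.41, camera adjusted p = 7.10e-04 at the preset correlation). This trend and an effect of TL1A cannot be told apart for this list, since that median met neither bound and its correlated genes make the interval too narrow.

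The Th17-associated list lay higher with TL1A, by a median log2 fold change of 1.47. The length and GC trend is argued against by its direction, since fold changes fell with length and rose with GC content. The list's median length was 3898 nucleotides and its GC content 46.8%, against 3376.5 and 49.4% over all tested genes. By these medians the trend would lower this list, so removing it could hardly have ended the rise. After removal the median was 1.46 (bootstrap interval 0.76 to 2.66), hardly moved from 1.47. It did not rise, so a lowering by the trend was not seen in the median. A single library is argued against as well, the highest adjusted p with 1 library left out being 1.69e-07. An effect of TL1A stays open as an untested explanation, and the set was not called with an estimated correlation (adjusted p = 0.287).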
